A study of Homo sapiens with 4 samples.

How the data were processed

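RNA of OCI-AML3 cells was sequenced in 4 libraries, 2 with the genotype Plex CEBPB and 2 with the genotype Plex Control. Per the labels, RNA was taken with a Qiagen RNeasy kit and poly(A) mRNA libraries were made with a stranded Illumina kit. The authors' processing notes name Trimmomatic 0.39, kallisto 0.46.2 and the GRCh38 build. The annotation release, the strand setting and the step from transcripts to genes are not stated.

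The deposited gene-level files hold expected counts (estimated counts, under the name raw counts), TPM, and a further unit, the effective length of each gene's transcripts in bases. In the deposited counts each value equals the gene's TPM multiplied by 1 constant per library, which gives the library its total, so these counts carry no transcript length and very short genes have more counts than reads. Reads were recovered as TPM times effective length, rescaled to the library total. Of the recovered values between 0.2 and 500, 58.7% to 60.8% lay within 0.01 of a whole number. Of 6641 identifiers past the threshold, 23 rested on fewer than 10 recovered reads in all 4 libraries and 34 had an effective length under 100 bases.

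The files list 41084 Ensembl identifiers, of which 35690 matched a gene symbol. Values of 1007 identifiers are identical to those of another, so their reads are not told apart. Identifiers without a symbol took 3.22% to 3.28% of TPM, and they were neither named nor summed with others. Coordinates and gene types come from GENCODE v29. Spearman correlations between libraries were 0.992 within controls, 0.990 within CEBPB and 0.923 between control 1 and CEBPB replicate 1. Against counting error alone, the chi-square per degree of freedom was 4.49 between the controls and 8.42 between the CEBPB libraries.

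Counts were rounded, filtered with filterByExpr by group (13698 identifiers left), scaled by trimmed mean of M values (factors 0.938 to 1.09) and tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test and Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 11.3%. There are 31 tested gene lists of 35 fixed ones. They were compared with other genes by camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and by fry, which asks whether a list moves on balance. With 4 libraries in 2 groups, the form with an estimated correlation has few degrees of freedom. The lowest adjusted p of any list in it was 0.598. A call lost there therefore does not show that correlation between genes undid it. Lists with under 5 measurable members were not tested. In each list the number of members past the threshold was also computed adjusted over the list alone.

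The test, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names CEBPB, IL1B, TNF, BCL2, MDM2, MCL1, BCL2A1, BCL2L1 and the other measured CEBP genes. It also names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean log2 CPM of 1 or more, a gene symbol, and both CEBPB libraries on 1 side of both controls. In each list it names up to 4 members with the smallest adjusted p, with 1 of each direction where both passed; 1 gene that this rule names is not reported here. Where a group had 0 reads, folds are given against a floor of 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% counting interval.

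Alternatives were DESeq2 size factors, upper-quartile scaling, library totals alone, no filter on low counts, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma on log2 TPM with 1 or 0.1 added, a fit without mitochondrial genes and CEBPB, a replicate block, a test against a 1.5-fold change, and each library left out in turn, where the lone library of a group is assumed to vary like the other group. Added after the data were seen were the recovered reads, these with a length offset, named identifiers without an identical partner, and a fit without WT1. Tested on simulated data with 13380 genes and the same design, the fit recovered 56.3% of 80 genes changed 1.5-fold, 73.8% of 80 genes changed 2-fold and 97.5% of 40 genes changed 4-fold, with 6 false calls. The simulation changed far fewer genes than the 6641 identifiers called in the data. Its counts were drawn at the fitted dispersion trend, without the length-free scaling of the deposited counts. These rates therefore need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.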

Results

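The series holds RNA sequencing of OCI-AML3 cells, a human acute myeloid leukaemia line. There were 4 libraries. In 2 of them the genotype label names CEBPB and in the other 2 it names a control. Both labels also carry the word Plex, which the sources used here do not explain. CEBPB encodes C/EBPβ, a transcription factor of inflammatory and myeloid genes. The series title sets the context: a loop between C/EBPβ and the cytokines IL-1β and TNFα in leukaemia cells that resist inhibitors of BCL2 and MDM2. The deposited counts summed to 19882347 and 21598592 in the control libraries and to 21950575 and 18151225 in the CEBPB libraries. These totals cover 41084 Ensembl gene identifiers. Levels below are given in TPM (transcript abundance scaled to the same sum in every library) as mean ± SD with n = 2 per group, and coordinates are those of GENCODE v29 on GRCh38.

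The CEBPB libraries held far more reads assigned to CEBPB than the controls and differed from them across much of the transcriptome. The alarmins S100A8 and S100A9, ARG1 and the survival gene BCL2A1 rose, while CEBPA, BCL2, MYC and 26 of 27 listed genes of ribosome biogenesis and MYC targets fell. IL1B was higher in both CEBPB libraries. The TNF identifier did not pass, and its call depended on the method and on 1 control library. Of 13698 identifiers tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3251 were higher and 3390 lower in the CEBPB libraries, and 7057 did not pass.

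CEBPB, identifier ENSG00000172216.6 (chromosome 20, 50190734 to 50192689, plus strand, a protein-coding gene), stood at 4.60 ± 0.171 TPM in the controls and 437 ± 139 TPM in the CEBPB libraries. Its log2 fold change was 6.38 (SE 0.26, adjusted p = 1.3e-04, edgeR), or 83.3-fold. The gene-level values do not tell reads of the cells' own CEBPB gene from those of an introduced copy, if there was one. IL1B, which encodes the cytokine IL-1β (ENSG00000125538.12, chromosome 2, 112829751 to 112836903, minus strand), was at 48.8 ± 3.03 TPM in the controls and 104 ± 28.1 TPM in the CEBPB libraries. That is a log2 fold change of 0.91 (SE 0.17, adjusted p = 0.0078, edgeR). Tested against a change of 1.5-fold instead of 0, its adjusted p was 0.0855. TNF, which encodes TNFα (ENSG00000232810.5, chromosome 6, 31575567 to 31578336, plus strand), read 1.31 and 39.0 TPM in control 1 and control 2 and 1.06 and 0.945 TPM in the CEBPB libraries. Its log2 fold change was -4.52 (SE 1.56, adjusted p = 0.0613, edgeR), short of the threshold. It passed with DESeq2 (adjusted p = 0.0267), with a replicate block (0.0323), with recovered reads (0.0291) and with these and a length offset (0.0386, edgeR), and not with limma-voom (0.412). Without control 2 the value was -0.58 (adjusted p = 0.536, edgeR), and without control 1 it was -5.47 (adjusted p = 1.9e-04, edgeR), so the value rests on control 2. Several genes near TNF on chromosome 6 held few reads under their own identifier, so the TNF values are uncertain.

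**Figure D1:**
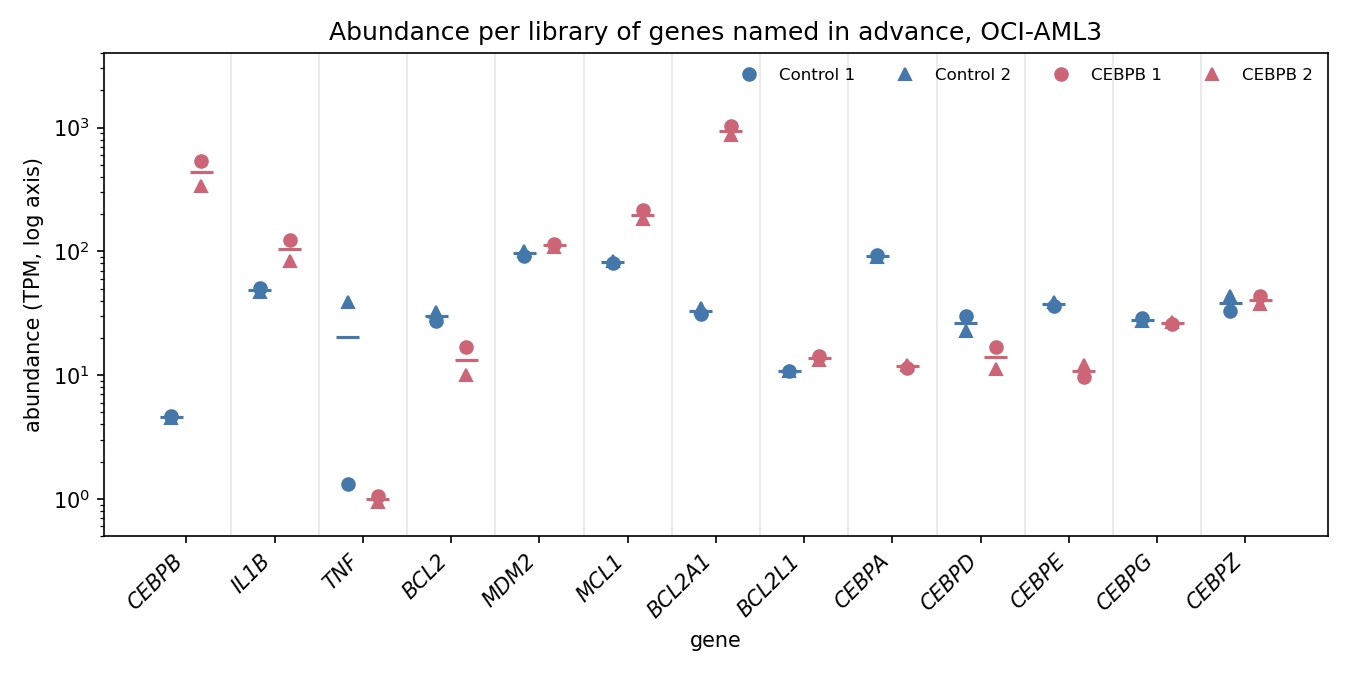
Abundance in TPM (vertical, log axis) of 13 genes named in advance, with 1 point per library (circles, replicate 1; triangles, replicate 2) and a bar at each group's mean. CEBPB and BCL2A1 lie far higher in the CEBPB libraries, CEBPA lies lower, and for TNF the 2 control libraries lie apart at 1.31 and 39.0 TPM.

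The other genes with a CEBP symbol moved against CEBPB or did not pass. CEBPA, a regulator of granulocyte commitment, fell from 91.4 ± 2.35 to 11.8 ± 0.411 TPM (-3.14, SE 0.09, adjusted p = 6.9e-05, edgeR). CEBPE fell from 37.5 to 10.8 TPM (-1.97 on the log2 scale) and CEBPD from 26.3 to 13.9 TPM (-1.09), CEBPD not passing the test against a 1.5-fold change (adjusted p = 0.0617, edgeR). CEBPG (-0.26, adjusted p = 0.0590, edgeR) and CEBPZ (-0.11, adjusted p = 0.570, edgeR) did not pass, and CEBPZ changed sign without control 2 (0.11) and with library totals (0.072). CEBPG passed with recovered reads (adjusted p = 0.0303, edgeR), with these and a length offset (0.0413) and among named identifiers without an identical partner (0.0486), and CEBPZ passed with recovered reads (-0.20, adjusted p = 0.0382, edgeR). In the list of the C/EBP family and partners, 5 of 14 members rose and 5 fell (5 and 6 adjusted over the list alone), and the competitive set test camera gave an adjusted p of 0.984. Among the partners, TRIB1, a pseudokinase that directs C/EBPα to degradation, rose from 7.89 to 202 TPM (4.5). BATF3 rose (1.05) and BATF fell (-2.61).

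The targets named in the title did not move together. BCL2 (chromosome 18, 63123346 to 63320128) fell from 30.1 ± 3.54 to 13.3 ± 4.79 TPM (-1.35, SE 0.22, adjusted p = 0.0054, edgeR). MDM2 (chromosome 12, 68808176 to 68850686) was at 96.1 ± 6.79 and 112 ± 5.10 TPM (0.04, SE 0.07, adjusted p = 0.706, edgeR), and at -0.034 on the log2 scale without control 1. With library totals MDM2 was at 0.22 (adjusted p = 0.0782, edgeR) and on log2 TPM also at 0.22 (adjusted p = 0.0600 and 0.0628, limma), short of the threshold. BCL2A1 (chromosome 15, 79960889 to 79971446), an anti-apoptotic relative of BCL2, rose from 33.1 ± 2.59 to 943 ± 112 TPM (4.65, SE 0.10, adjusted p = 3.9e-05, edgeR). MCL1, another anti-apoptotic member, rose from 81.7 ± 1.73 to 198 ± 24.3 TPM (1.10, SE 0.08, adjusted p = 4.7e-04, edgeR). BCL2L1, which encodes BCL-XL, was at 10.7 and 13.8 TPM (0.18, adjusted p = 0.193, edgeR), and passed with library totals (0.36, adjusted p = 0.0439, edgeR) and on log2 TPM (adjusted p = 0.0422 and 0.0447, limma). In the whole BCL2 family list 4 of 18 measured members rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.650). Without either control library, and without CEBPB replicate 1, 2 members rose. The pro-apoptotic BBC3 (PUMA) fell from 23.0 to 9.32 TPM (-1.48) and cytochrome c (CYCS) fell by 0.67 on the log2 scale. Of 29 p53 target genes 4 rose and 15 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0639). CDKN1A, which encodes the cell cycle inhibitor p21, fell from 244 to 86.5 TPM (-1.67) and PHLDA3 fell (-1.07), while the death receptor gene FAS rose from 8.83 to 32.7 TPM (1.71).

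Genes of IL-1, TNF and chemokine signalling rose more often than they fell, cytokine receptors fell more often, and camera called none of these 4 lists. Fry, which called 22 of the 31 tested lists, placed the IL-1 (adjusted p = 0.0036), TNF (0.020) and chemokine (0.0036) lists upward. It did not call the receptors (adjusted p = 0.211). In IL-1 signalling and the inflammasome, 12 of 22 measured members rose and 5 fell (camera adjusted p = 0.193). IL1RAP, the accessory chain of the IL-1 receptor, rose from 13.2 to 89.1 TPM (2.58), and CASP1, the protease that matures IL-1β, rose from 68.5 to 179 TPM (1.21). NLRP3 (-1.50) and PYCARD (-1.39), the sensor and adaptor of an inflammasome, fell. In TNF and NF-κB signalling, 12 of 29 rose and 6 fell, with 12 and 7 adjusted over the list alone (camera adjusted p = 0.109). TNFAIP6 rose from 6.43 to 229 TPM (4.98), the mitochondrial superoxide dismutase SOD2 from 119 to 671 TPM (2.31) and CFLAR by 1.38 on the log2 scale, while the NF-κB inhibitor TNFAIP3 fell (-0.84). Of 15 chemokines and secreted cytokines 10 rose and 3 fell, with 10 and 4 adjusted over the list alone (camera adjusted p = 0.0639, against 0.0455 without control 1 and 0.0497 without control 2). The other 20 of the 35 members of that list did not pass the filter on low counts, IL6 and CSF2 among them. CXCL1 rose from 2.0 to 57.7 TPM (4.66), CCL20 from 2.74 to 69.8 TPM (4.49) and VEGFA from 21.8 to 84.3 TPM (1.77). CCL5 fell from 125 to 20.7 TPM (-2.77). Of 25 cytokine and growth factor receptors 6 rose and 12 fell, with 6 and 13 adjusted over the list alone (camera adjusted p = 0.243). The complement receptor C3AR1 (4.49, 4.89 to 125 TPM) and IFNGR1 (1.31) rose, and IL6R (-2.28) and CCR2 (-3.54, 22 to 2.17 TPM) fell. For the IL-1 list the counts adjusted over the list alone were the same as over all genes.

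Of the listed neutrophil genes with enough counts to test, most rose. Of 17 measured genes of secondary granules and neutrophils 14 rose and 3 fell, with the same counts adjusted over the list alone, and camera placed the list above other genes (adjusted p = 3.6e-05). With an estimated correlation between genes that call was lost (adjusted p = 0.598). No list was called in that form, so this does not decide whether correlation between genes accounts for the call. The other 9 of the 26 members had too few counts to test. These were CAMP, MMP9, CEACAM8, CEACAM1, OLFM4, PGLYRP1, CRISP3, CD177 and FCGR3B, at 0.413 TPM or less in each library. S100A8 and S100A9, the calprotectin subunits, rose from 153 ± 3.93 to 5096 ± 56.4 TPM (4.88) and from 284 ± 2.48 to 4679 ± 229 TPM (3.86). ARG1, arginase 1, rose from 0.474 ± 0.0771 to 786 ± 92.8 TPM (10.47). ORM1, an acute-phase glycoprotein, fell from 515 to 218 TPM (-1.41). Primary granule and progenitor genes went the other way more often, with 4 of 17 rising and 8 falling and the same counts adjusted over the list alone (camera adjusted p = 0.328). AZU1, azurocidin, fell (-2.35), while SERPINB1 (0.93), GFI1 (0.86) and RNASE3 (1.30) rose.

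Monocyte and macrophage markers split, with 9 of 27 rising and 12 falling and the same counts adjusted over the list alone (camera adjusted p = 0.917). Lysozyme (LYZ) rose from 1360.2 ± 74.2 to 7804 ± 166 TPM (2.34), MNDA from 80.3 to 483 TPM (2.41) and EGR1 from 3.01 to 37.6 TPM (3.47). IRF8, a transcription factor of monocytes and dendritic cells, fell from 166 to 39.9 TPM (-2.24). Of 17 measured stem and progenitor genes of acute myeloid leukaemia 4 rose and 9 fell, with 4 and 10 adjusted over the list alone (camera adjusted p = 0.0639). The other 13 of the 30 members had too few counts to test, CD34 and KIT among them. MYC (-1.80, 237 to 77.3 TPM), the receptor kinase FLT3 (-2.02, 30.7 to 8.59 TPM) and LMO2 (-1.23) fell, and PBX3 rose (0.81). Scaled by library totals alone, camera called this list lower (adjusted p = 0.033).

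Many genes of ribosome production and oxidative phosphorylation fell, and outside ribosome biogenesis most of these changes were small. Tested against a 1.5-fold change, 22 of 27 genes of ribosome biogenesis and MYC targets fell, 2 of 29 cytosolic ribosomal protein genes, 1 of 31 nuclear genes of oxidative phosphorylation and 0 of 13 mitochondrially encoded genes. Of 27 genes of ribosome biogenesis and MYC targets 26 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.7e-09, and adjusted p = 0.598 with an estimated correlation). NPM3 fell from 135 to 43.9 TPM (-1.80), the spermidine synthase gene SRM from 156 to 56.0 TPM (-1.66) and BOP1 by 1.54 on the log2 scale. Of 29 cytosolic ribosomal protein genes 27 fell and 0 rose, with 28 falling adjusted over the list alone (camera adjusted p = 2.8e-07, and adjusted p = 0.598 with an estimated correlation). RPLP2 (-0.75), RPL3 (-0.74), RPL13 (-0.71) and RPLP1 (-0.64) led them. Reads of ribosomal protein genes are shared with processed pseudogenes, so single values are uncertain. Of 31 nuclear genes of oxidative phosphorylation 22 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.2e-04, and adjusted p = 0.598 with an estimated correlation). NDUFV1 (-0.84), COX5A (-0.64) and NDUFB8 (-0.66) fell and NDUFA4 rose (0.35). Without control 1, 13 of these fell and 0 rose, as NDUFA4 did not pass (adjusted p = 0.111, edgeR). Of 13 mitochondrially encoded genes 6 fell and 0 rose, with 8 falling adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.608 with an estimated correlation). Fry did not call this list (adjusted p = 0.116). MT-ND3 (-0.30), MT-CO2 (-0.36), MT-ATP8 (-0.33) and MT-CO3 (-0.37) fell. These 4 did not pass without control 2 (adjusted p from 0.0953 to 0.122, edgeR), nor did MT-ND3 (0.0655) and MT-CO2 (0.0531) without control 1 or MT-ATP8 (0.0526) without CEBPB replicate 1. They did not pass on log2 TPM either (adjusted p from 0.0649 to 0.136, limma). In the list 2 genes fell when libraries were scaled by their totals or control 1 was left out, 0 without control 2, 12 without CEBPB replicate 2, 11 with a replicate block and 9 with recovered reads and a length offset, and camera lost it with library totals (adjusted p = 0.060), without control 2 (adjusted p = 0.099) and without CEBPB replicate 1 (adjusted p = 0.067).

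Of 25 glycolysis genes 5 rose and 14 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.109). Tested against a 1.5-fold change, 3 glycolysis genes rose and 1 fell. PFKL (-1.12) and LDHB (-0.74) fell, and the glucose transporter SLC2A3 (1.74, 11.8 to 44.5 TPM) and PFKFB3 (1.15) rose. Without control 1, 3 rose and 9 fell, and without control 2, 3 rose and 8 fell. Camera called the list lower without CEBPB replicate 2 (adjusted p = 0.0468). Of 38 cell cycle genes 8 rose and 17 fell, with 8 and 20 adjusted over the list alone (camera adjusted p = 0.193). Against a 1.5-fold change 3 cell cycle genes rose and 3 fell. The inhibitor CDKN2C (1.23) and the ribonucleotide reductase subunit RRM2 (1.20, 334 to 868 TPM) rose, and CDK4 (-0.84) and MCM2 (-0.75) fell. Scaled by library totals, 12 cell cycle genes rose and 11 fell, and without control 2, 7 rose and 11 fell. Of 15 histone genes 5 rose and 0 fell, with 4 rising adjusted over the list alone (camera adjusted p = 0.145), among them H2BC12 (0.99), H2BC5 (1.23), H4C8 (1.40) and H2BC4 (1.13). Without control 1, 2 histone genes rose, and 3 without control 2 or without CEBPB replicate 2. H4C8 did not pass without control 1 (adjusted p = 0.0552, edgeR) or control 2 (0.0644), nor H2BC4 without control 1 (0.0514) or CEBPB replicate 2 (0.0520). Most histone mRNAs lack a poly(A) tail, for which these libraries were selected.

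Interferon and stress genes rose more often than they fell. In the type I interferon list 13 of 32 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.598 with an estimated correlation). Fry did not call this list (adjusted p = 0.0592). GBP1 (4.96, 1.56 to 54.8 TPM), the RNA sensor IFIH1 (1.28) and HERC5 (1.36) rose and IFI44 fell (-0.62). In iron and heme handling 11 of 17 rose and 2 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.598 with an estimated correlation). Heme oxygenase HMOX1 rose from 9.66 to 78.9 TPM (2.85), and the antioxidant genes GCLM (1.31) and SRXN1 (0.99) rose, while the ferrireductase gene STEAP3 fell (-1.74). With any 1 of the 4 libraries left out, 1 member of this list fell. In the unfolded protein and amino acid stress response 11 of 21 rose and 4 fell, with 12 and 5 adjusted over the list alone (camera adjusted p = 0.0639). DNAJB9 (3.17, 5.38 to 54.8 TPM), the chaperone HSPA5 (1.05) and the cystine transporter SLC7A11 (1.06) rose and DDIT4 fell (-1.02), and 2 members fell with library totals. In the JAK-STAT3 and SOCS response 8 of 19 rose and 4 fell, with 8 and 5 adjusted over the list alone (camera adjusted p = 0.297). BCL6 (2.31), STAT3 (1.35) and LRG1 (1.41) rose and FOS fell (-1.0), and 2 members fell without control 1, control 2 or CEBPB replicate 1.

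Lipid and membrane genes divided within each list. Of 10 eicosanoid genes 4 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.780). PTGS2, the inducible cyclooxygenase, rose from 0.908 ± 0.234 to 222 ± 19.9 TPM (7.77), and LTA4H (1.41) and PLA2G4A (1.80) rose, while its constitutive counterpart PTGS1 fell from 20.1 to 6.65 TPM (-1.77). The median of this list was -0.87, yet the rotation test fry placed its balance upward (adjusted p = 0.024). Of 27 genes of cholesterol and fatty acid synthesis 10 rose and 5 fell, with 12 and 7 adjusted over the list alone (camera adjusted p = 0.243). HMGCS1 (1.68) and CYP51A1 (1.38) rose and FABP5 fell (-1.72), and 8 members fell without CEBPB replicate 2. With library totals 13 members rose and 3 fell, and with a replicate block or with recovered reads and a length offset 11 rose and 8 fell. In lysosome and autophagy 12 of 28 rose and 5 fell, with 13 and 7 adjusted over the list alone (camera adjusted p = 0.243). ASAH1 (1.59), SQSTM1 (1.54) and WIPI1 (2.70) rose, and TFEB, a transcription factor of lysosomal genes, fell (-1.90). Of 14 complement and coagulation genes 8 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.282). CD55 rose from 71.5 to 638 TPM (2.98) and PLAUR from 119 to 360.1 TPM (1.42), and PLAU, which encodes the ligand of that receptor, fell from 16.5 to 1.54 TPM (-3.61). Of 24 adhesion genes 5 rose and 9 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.297). The integrin chains ITGAL (-2.73, 131 to 22.4 TPM) and ITGA4 (-1.82) and the hyaluronan receptor CD44 (-1.70) fell, and galectin 3 (LGALS3) rose (0.90).

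Antigen presentation genes were hard to read, because several genes of the major histocompatibility complex held few reads under their own identifier. Of 14 class I genes 3 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.790). PSMB10 (-1.50) and TAP2 (-1.53) fell and NLRC5 (1.00) and B2M (0.38) rose. Without control 2, 1 member rose, and B2M did not pass (adjusted p = 0.0795, edgeR). Of 5 measurable members of the class II list 2 fell and 0 rose, with 3 falling adjusted over the list alone (camera adjusted p = 0.109). The 2 that fell over all genes were CD74 (-1.15, 170.2 to 86.6 TPM) and CTSS (-0.55). The other 10 of the 15 members had too few counts to test, among them CIITA, at 0.249 TPM or less in each library. Low expression of these 10 was not told apart from reads held under other identifiers. RFX5 (-0.28) and RFXAP (-0.19) did not pass, and RFX5 passed without CEBPB replicate 2 (adjusted p = 0.0257, edgeR), with DESeq2 (0.0467), with recovered reads (0.0045), with these and a length offset (0.0402) and among named identifiers without an identical partner (0.0448).

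**Figure D2:**
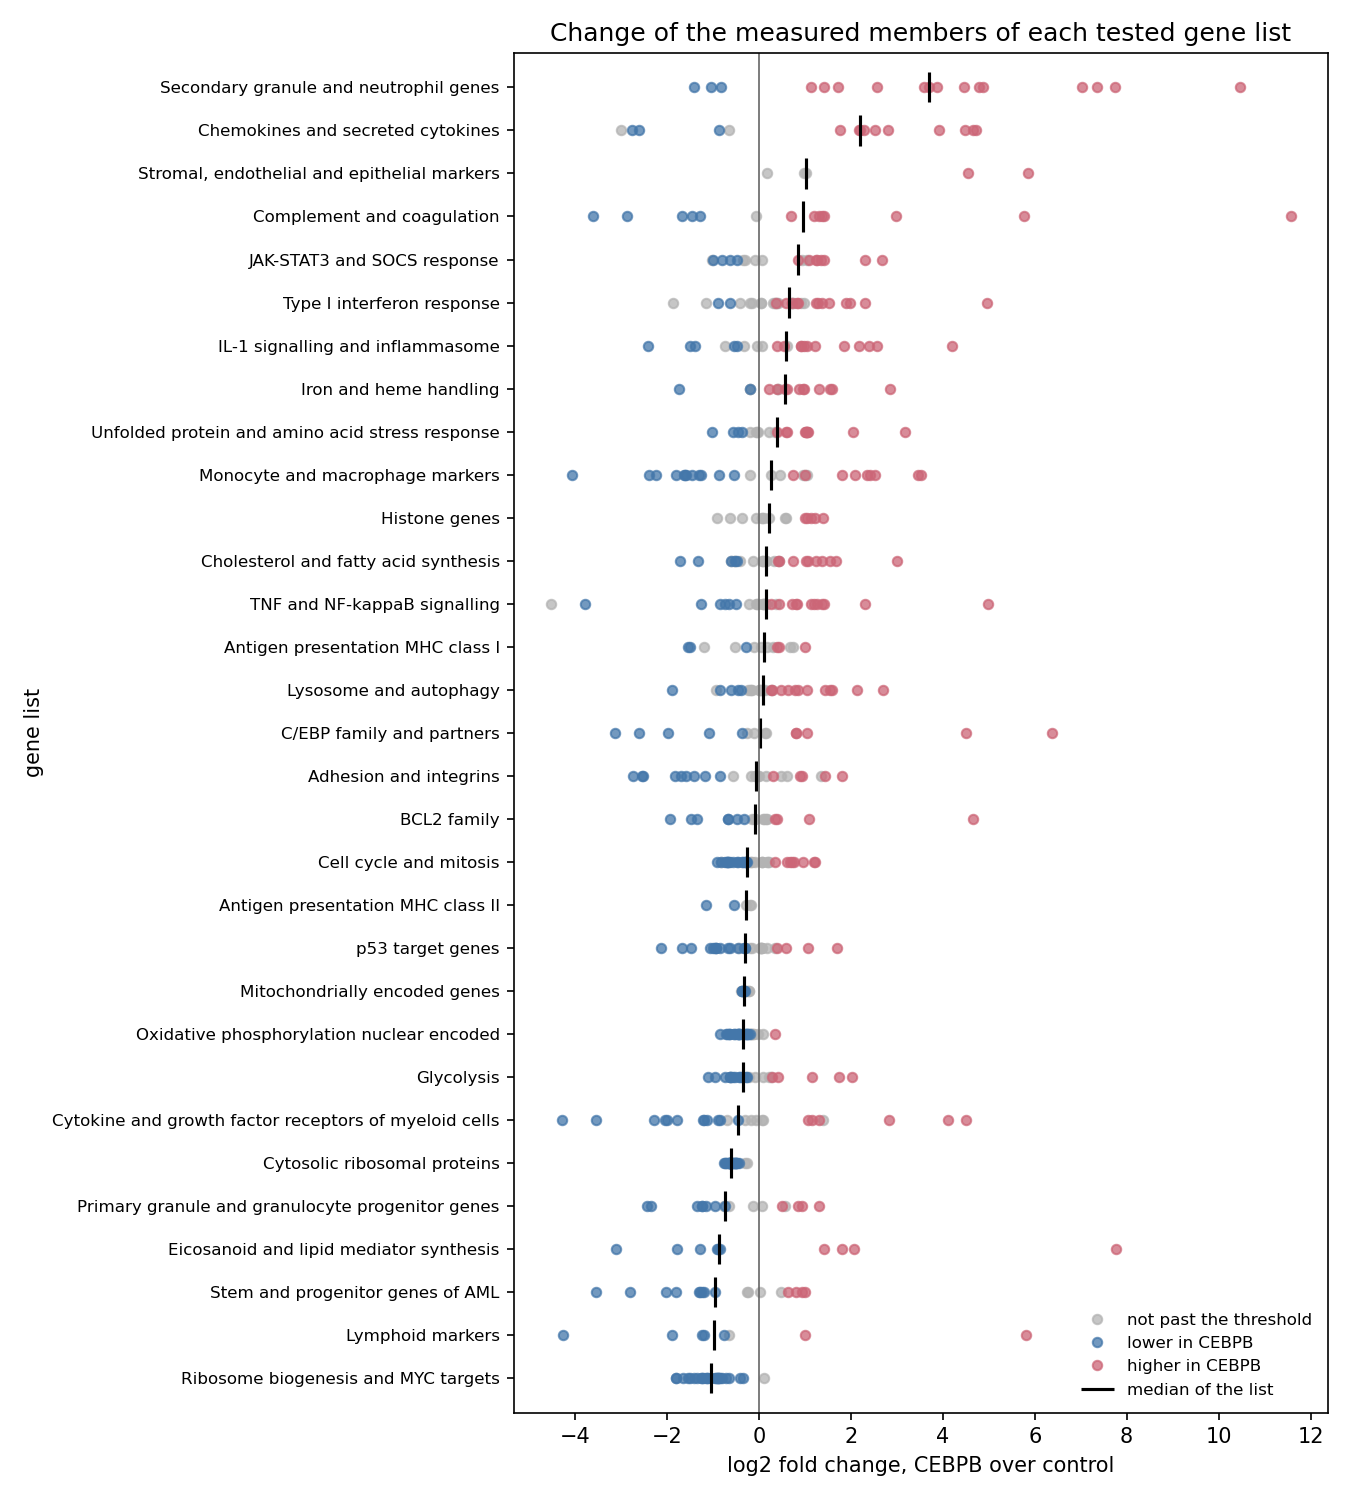
Log2 fold change of CEBPB over control (horizontal) for each measured member of the 31 gene lists tested (vertical, ordered by median). Red points passed the threshold upward, blue points downward and grey points did not pass, and the black bar is the list's median. In ribosome biogenesis and MYC targets 26 of 27 members lie lower, and in secondary granule and neutrophil genes 14 of 17 lie higher.

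Markers of other cell types were mostly near 0 in all 4 libraries. Erythroid (2 of 17 members measurable), megakaryocyte (2 of 13), eosinophil, basophil and mast cell (3 of 16) and dendritic cell (3 of 16) lists had too few measurable members for a set test. In these, TFR2 fell (-1.39, 5.08 to 2.21 TPM) and EPOR did not pass (-0.22). THBS1 rose (1.31), and GP9 was lower in the CEBPB libraries, 26 reads against 3, a ratio of 8.38 with a 95% counting interval of 2.57 to 43.3. PRG2 fell (-2.94, 8.64 to 1.30 TPM), RNASE2 rose (0.49) and CCR3 did not pass (-0.56, and 0.029 without control 2). BATF3 rose (1.05), and CLEC9A (-0.21) and TCF4 (-0.04) did not pass, TCF4 changing sign without control 2 (0.088), without CEBPB replicate 2 (0.070) and with library totals (0.14). TFR2 did not pass without control 2 (adjusted p = 0.0944, edgeR) or CEBPB replicate 1 (0.0526), GP9 without control 1 (0.0610), CEBPB replicate 1 (0.0719) or CEBPB replicate 2 (0.104), and RNASE2 without control 1 (0.0682). The counts adjusted over the list alone were the same in these 4 lists, with 0 rising and 1 falling in the erythroid list, 1 and 1 in the megakaryocyte list, 1 and 1 in the eosinophil list and 1 and 0 in the dendritic list.

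Of 8 measurable lymphoid markers 2 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.193). GNLY rose from 1 read to 85 (over both libraries of a group, a ratio of 87.9 with a 95% counting interval of 15.4 to 3513). CD79B (-1.90, 5.87 to 1.77 TPM), NKG7 (-1.23) and CD4 (-0.76) fell. NKG7 also stands in the primary granule list, and CD4 is expressed by monocytes. Without control 2, 3 markers fell, and without control 1 or either CEBPB library 1 rose. Of 5 stromal, endothelial and epithelial markers 2 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0443, and adjusted p = 0.598 with an estimated correlation). The matrix proteoglycans lumican (LUM) and decorin (DCN) rose from 1.21 to 79.5 TPM (5.86) and from 0.802 to 20.6 TPM (4.55), while the fibroblast collagen COL1A1 was at 0.591 and 1.38 TPM and ACTA2 at 0.518 and 1.19 TPM, neither past the threshold. With recovered reads COL1A1 passed upward (1.60, adjusted p = 0.0010, edgeR). Camera lost this list with library totals (adjusted p = 0.061) and without CEBPB replicate 1 (adjusted p = 0.052).

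Among genes named by rule, the largest increases were in genes with no or few reads in the controls. SERPINB2, plasminogen activator inhibitor 2 (chromosome 18, 63871692 to 63903890), rose from 0.0861 ± 0.0333 to 268 ± 38.6 TPM (11.56, SE 0.21, adjusted p = 2.2e-05, edgeR). P2RY13, a purinergic receptor (chromosome 3, 151326312 to 151329548), rose from 0.0577 ± 0.0191 to 99.7 ± 5.84 TPM (10.67, SE 0.21, adjusted p = 3.1e-05, edgeR). PI3, the elastase inhibitor elafin (chromosome 20, 45174876 to 45176544), had 0 reads in the controls and 58.8 ± 2.19 TPM in the CEBPB libraries, at least 362-fold higher against a floor of 3 reads over the group. By the same floor CYP3A7 was at least 172-fold higher, the pseudogene OFCC1 at least 62.1-fold, CLVS1 at least 34.5-fold, VCX at least 32.8-fold and the T cell receptor gamma joining segment TRGJP2 at least 11-fold. CYP3A7 and VCX belong to families of closely similar genes and are uncertain. TRGJP2 rested on 32 reads over an effective length of 17.0 to 18.4 bases. RPL39P34 also met the rule for the largest changes but rested on 3 reads in all, so no fold is given. ARG1, described above, completes these 10.

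The largest decrease was that of WT1, which encodes the Wilms tumour transcription factor (ENSG00000184937.16, chromosome 11, 32387775 to 32435630, minus strand). It stood at 31498 and 30075 TPM in the controls and at 7.71 and 7.56 TPM in the CEBPB libraries (-12.16, SE 0.08, adjusted p = 9.8e-07, edgeR). The effective transcript length deposited for WT1 was 453 and 425 bases in the controls and 1668 and 1576 bases in the CEBPB libraries, so reads in the 2 groups were assigned to different WT1 transcripts on average. CD180, a Toll-like receptor homologue, fell from 5.40 ± 0.0157 to 0.0412 ± 0.0282 TPM (-7.60, SE 0.56, adjusted p = 4.9e-04, edgeR), the fucosyltransferase FUT7 from 11.2 ± 1.42 to 0.261 ± 0.263 TPM (-5.61) and ABI3 from 8.81 ± 1.11 to 0.362 ± 0.0278 TPM (-4.81). NTSR1 (-4.71), IGLL5 (-5.80, 22.4 to 0.46 TPM) and LRTM2 (-6.79) fell. The values of LRTM2 are identical to those of another identifier, so its reads are not told apart. RHEX was lower in the CEBPB libraries, with 145 reads against 3, a ratio of 46.7 with a 95% counting interval of 15.7 to 229. The immunoglobulin lambda joining segments IGLJ1 and IGLJ2 had 0 reads in the CEBPB libraries against 12 and 6 in the controls, at least 3.87-fold and 1.93-fold lower. IGLL5 overlaps IGLJ1. Intervals and floors here cover counting error only.

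**Figure D3:**
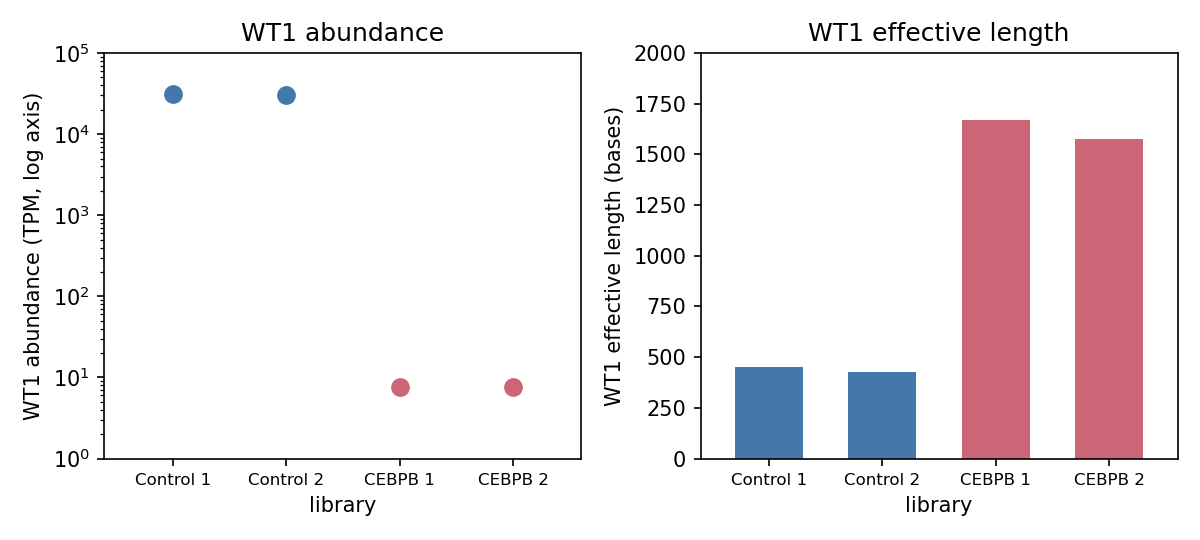
WT1 abundance in TPM (left, log axis) and WT1 effective length in bases (right) in each of the 4 libraries, with controls in blue and CEBPB libraries in red. Controls combine 31498 and 30075 TPM with lengths of 453 and 425 bases, and CEBPB libraries combine 7.71 and 7.56 TPM with lengths of 1668 and 1576 bases.

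Changes of at least 2-fold were found for 1166 of the higher and 1093 of the lower identifiers, and changes of at least 4-fold for 443 and 293. Of the 13698 identifiers tested, 12584 have a gene symbol, and 3018 of the higher and 3032 of the lower are annotated as protein-coding. Tested against a change of 1.5-fold, 1186 were higher and 1188 lower. Scaled by library totals alone, 4424 were higher and 2360 lower, so 65.2% of calls were higher against 49.0% with the trimmed-mean scaling, and the median of all identifiers shifted by 0.18 on the log2 scale. All changes above are relative to the trimmed-mean scaling. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.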

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

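The tests of WT1 effective length and of lengths separated by 1.5-fold were chosen only after the result was seen. In the report the effective lengths served to recover reads and to describe WT1 and TRGJP2. A planned test with limma compared them between groups and called 0 of 10038 identifiers at an adjusted p under 0.05, with 1701 at an unadjusted p under 0.05 against 501.9 expected. On simulated lengths with an assumed noise, the same test called 31 of 100 identifiers changed 1.5-fold. The 0 calls therefore do not exclude changes of that size. In a count made afterwards on these 10038 identifiers, 22 had lengths in both CEBPB libraries at least 1.5-fold above (14) or below (8) those in both controls. The other ways to split the 4 libraries into pairs gave 6 and 8. No biological explanation was tested for this.

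WT1 was the clearest single case, at 31498 and 30075 TPM in the controls and 7.71 and 7.56 TPM in the CEBPB libraries. Full-length WT1 mRNA as the bulk of the control signal was argued against, because the highest effective length there was 453 bases, against 1668 and 1576 bases in the CEBPB libraries. This length is a mean weighted by abundance, so a smaller amount of full-length WT1 mRNA in the controls is not excluded. WT1 took 3.15% and 3.01% of TPM in the controls. Leaving it out gave 6640 identifiers past the threshold against 6641, with 6627 called in the same direction in both. The median log2 fold change shifted by 0.0011. The trimmed-mean scaling used here, which sets such genes aside, was thus hardly moved by WT1. How its share acts on library totals is not decided, since the fit without WT1 was not run with that scaling. Where the short WT1 sequence came from was not tested, and it may be a cellular transcript or introduced sequence.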

How the results depend on the processing

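The recovered reads, these with a length offset, named identifiers without an identical partner and the fit without WT1 were tests chosen only after the data were seen. The planned length offset on the deposited counts was not run, because those counts already leave length out.

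The numbers of higher and lower identifiers stayed within 1.5 times under every alternative except the test against a 1.5-fold change, which left 1186 higher and 1188 lower. With a replicate block there were 3174 and 3308, and same-numbered libraries did not vary together (correlation -0.013). Leaving out single libraries gave 2289 to 2820 higher and 2398 to 3063 lower. Of 6641 identifiers past the threshold, 6340 also passed in the same direction with recovered reads and 2 in the opposite direction. With recovered reads and a length offset, 6321 passed in the same direction and 0 in the opposite one. The 2 reversals were thus not seen once effective length was taken into account. Among the genes named, 22 are called in the main test but not against a 1.5-fold change: IL1B, CEBPD, PBX3, CYCS, IFI44, CTSS, B2M, LDHB, COX5A, NDUFB8, NDUFA4, MT-ND3, MT-CO2, MT-ATP8, MT-CO3, H2BC4, RPLP1, RPL13, TFR2, GP9, RNASE2 and CD4. CEBPB passed wherever it was fitted (6.07 to 6.65).

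IL1B passed under every alternative but the 1.5-fold test (0.91, adjusted p = 0.0855), with 0.65 to 1.13 when single libraries were left out. TNF passed with DESeq2 (-4.53, adjusted p = 0.0267), a replicate block (-3.69, 0.0323), recovered reads (-5.78, 0.0291) and these with a length offset (-4.59, 0.0386), and ranged from -5.47 without control 1 (1.9e-04) to -0.58 without control 2 (0.536). The cause was not tested for the differing tools, and the leave-one-out range follows from control 2 alone holding a high value.

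Of the genes that did not pass, some changed sign. MDM2 went to -0.034 without control 1 (highest 0.11 without a single library), and was at 0.22 with library totals and on log2 TPM. CEBPZ went to 0.072 with library totals, 0.080 with log2 TPM plus 1 and 0.083 with log2 TPM plus 0.1, and ran from -0.30 without control 1 to 0.11 without control 2. TCF4 went to 0.14, 0.12 and 0.13 under the same 3 settings, and ran from -0.16 without control 1 to 0.088 without control 2, with 0.070 without CEBPB replicate 2. CCR3 ran from -1.44 without CEBPB replicate 1 to 0.029 without control 2. The cause was not tested.

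Of the 8 lists that camera called, 0 were called with an estimated correlation (adjusted p = 0.598 or 0.608), and fry called 22 lists, 6 of these 8 among them. Of these 8, fry did not call type I interferon (adjusted p = 0.0592) or the mitochondrially encoded genes (0.116). The form with an estimated correlation has few degrees of freedom with 4 libraries, and it called 0 lists in all. There the stromal list lost its call although its estimated correlation of -0.159 lay below the preset 0.01. For eicosanoid synthesis fry pointed up (adjusted p = 0.0237) where camera and the median pointed down. Effective length gave 1 identifier past the threshold with a mean count of at least 1000 and 1 with a replicate block, against 0. The cause of the differences with fry and in the lengths was not tested. Depth limits genes with few reads, and the 2 libraries per group limit small changes.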

Other observations

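The tests of the chemokine ratio, of the region around TNF and of the lymphoid median were planned before their results were seen. The share without TNF and TRIM27, the TNF effective lengths and the single lymphoid and receptor genes were not part of that plan. The genes of the next paragraph were chosen after their values were seen.

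Outside the gene lists, several abundant genes changed at least 4-fold. NAMPT, an enzyme of NAD synthesis, rose from 180.1 to 1777 TPM (3.12) and ANXA1, annexin A1, from 12.2 to 1255 TPM (6.51). Lipoprotein lipase (LPL, 2.36) and HIF1A (2.35) rose. CORO1A, a leukocyte actin regulator, fell from 471 to 126 TPM (-2.08), and S100A4 (-2.54), LGALS9 (-2.27) and TASL (-3.40) fell.

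The TNF identifier read 1.31 TPM in control 1 and 39.0 TPM in control 2. A higher share of stimulated monocytes in control 2 was argued against, because the median log2 ratio of control 2 over control 1 in the chemokine list was -0.072. Reads divided among copies on alternative haplotype sequences remain a candidate explanation: 18 of 89 identifiers in the region (20.2%) differed over 2-fold between replicates, above the 95th percentile of 10000 matched random sets (15.7%, highest 22.5%). Without TNF and TRIM27, already seen, the share was 18.4% against 16.1%. The effective length of the TNF identifier was 1790 bases in control 2, on 1284 reads. It was 868, 815 and 694 bases in control 1, CEBPB replicate 1 and CEBPB replicate 2, on 20, 14 and 9 reads. Reads in control 2 were thus assigned to longer TNF transcripts on average. Whether the copies hold the missing TNF reads was not tested.

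Immunoglobulin lambda segments were found in the controls and T cell receptor gamma segments in the CEBPB libraries. IGLC2 read 35.3 and 31.5 TPM in the controls against 1.00 and 2.55 TPM, and TRGC2 0.593 and 0.636 TPM against 14.7 and 14.9 TPM. The highest median of the 21 lymphoid markers in any library was 0.0917 TPM. These mix T, B and NK cell genes, so cells of a single lineage could leave the median near 0, and it cannot exclude lymphoid cells. CD3E, CD2 and TRBC1 were at 0 and CD3D at 0.248 TPM or less, which argues against T cells. For B cells the controls were divided. MS4A1 read 0 and 0.0264 TPM and CD79A 0.432 and 0.283 TPM there, against 1.12 and 1.01 TPM for PAX5 and more for CD79B. Some markers moved with the segments: CD79B read 5.97 and 5.77 TPM in the controls against 2.22 and 1.32 TPM, and GNLY went from 1 read to 85. In each library 2 or 3 of the 21 markers stood at 5 TPM or more. Transcription of these segments in the leukaemia cells stays open and was not tested.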
